A study of Mus musculus with 2 samples.

How the data were processed

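The deposited files were filtered matrices of UMI counts for 1 control and 1 SHP099 library, made with Cell Ranger on mm10, also called GRCm38, per the submitters' processing notes. The file headers name output format 3.1.0 of that software, and its version and gene annotation are not given in the sources used here. Libraries came from the 10x Chromium 3' protocol and were read as 150-bp pairs on an Illumina HiSeq instrument, and tumours were dissociated with a kit, with no sorting step mentioned. Each matrix held 31053 features, of which 71 share a symbol with another and were kept apart by their gene identifier. The counts were used as they stand.

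Barcodes were kept with at least 200 genes and at most 20% of UMIs from mitochondrial genes. In the control library 99 barcodes failed the first limit and 282 the second, and in the SHP099 library 103 and 333. Scrublet, run per library within scanpy with its automatic threshold and an expected rate that grows with the number of barcodes, called 264 doublets in control and 198 in SHP099, which were removed. These are 3.32% and 2.51% of the barcodes that passed, fewer than the 6.36% and 6.32% expected. Doublets of cells of the same type remain.

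Counts were scaled to a common total per cell and put on a log scale. Genes found in at least 10 cells gave 2000 variable genes. Genes of the function lists and mitochondrial, ribosomal, haemoglobin and immunoglobulin genes were left out, so that clusters were not made by the listed genes. Single genes outside the lists, such as Ogn and Tgfb3, were not left out and could shape the clusters. The cells of both libraries were clustered together without integration, from 30 principal components and 15 neighbours by the Leiden method at resolution 1.0 with seed 1. T and NK cells were clustered again on their own with the same settings. Tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9.

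Each cluster took the name of the marker list with the highest mean log2 level over the 25th percentile across clusters, if at least 3 of its markers were found in 10% of cells and 2 times above the rest. Clusters whose Xist level lay under 0.1 of the median cluster were kept apart as Xist-negative. Macrophage and monocyte clusters were joined as mononuclear phagocytes, and cluster 13 carried markers of both.

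Shares of cells have exact binomial intervals. Within a class, UMIs were summed per library and divided by the class total to give CPM, with exact Poisson intervals, and log2 ratios of SHP099 over control used a prior of 0.5 CPM. The intervals of the ratios leave the prior out. Classes were compared where each library held at least 200 cells. List medians used members at 10 CPM or more in either library, and their percentile came from 10000 random lists of the same size matched in 25 bins of expression. Shares of cells with a UMI were taken after drawing each cell down to 2000 UMIs, leaving out shallower cells. Cells are not replicates, so no test, p-value or standard error was computed.

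Genes were named by a rule set before the data were examined. In each compared class these were the 10 genes with the largest and the 10 with the smallest log2 ratio among those with at least 50 CPM in 1 library, UMIs in 10% or more of its cells, a class level at least 0.25 of that in the class where the gene is highest, and the same direction when each cell counts alike. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, Xist, Y-linked and predicted genes were left out. Over all cells 5 and 5 were taken. For each described list the 2 highest and 2 lowest members could be named, and a fixed panel that included Ptpn11, Ifit1, Cxcl9, Cxcl10 and Pdcd1 was always allowed. Beyond these, marker genes and genes that define clusters were named only to describe the classes and clusters, the latter after they were seen. Positions came from GENCODE M21 on GRCm38 for all 89 genes looked up, which were those of the rule, the panel and a few others. Many list members and markers named in the text were not looked up.

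The filters, clustering settings, gene lists, marker lists, naming rule and the first set of alternatives were fixed before the data were examined. After the data were seen, the baseline of the marker scores was set to the 25th percentile, Xist-negative clusters were kept apart, and macrophage and monocyte lists were counted as 1 class. The rule had foreseen a tumour cell class, and the Xist-negative cells took its place. Alternatives added after the data were seen were clusters weighted alike, phagocytes without cluster 14 and T cells from cluster 3 alone. The main results followed through the alternatives, 4 share ratios and 6 list medians, were also picked once their values were known. The alternatives were first run over all lists in every class and then limited to the lists described for each class, which left 9 and 8 reversed values under planned and added alternatives and dropped a similar number for lists that the text does not use.

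The tests of explanations used genes specific to 1 class at 12 times the level of the other. A higher first limit left only Dcn for Xist-negative cells, so it was lowered after that was seen, and the outcome of the tests run at that time did not differ. The bound for calling an explanation excluded was loosened once and then put back to the one set at first.

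As a check of the method, Poisson counts were simulated with 200 changed genes per class. Variation beyond counting error was not simulated, so the check covers the calculation and not the spread of real counts. The intervals of unchanged genes covered the true value for 94.3% of genes in Xist-negative cells, 95.2% in phagocytes and 96.1% in T cells. Of genes changed by 1.5-fold, 100% were recovered in Xist-negative cells, 97.0% in phagocytes and 58.2% in T cells, where depth is low. Reads were not analysed here, so alignment, splice forms and variants were left out, and classes under 200 cells, such as NK cells, fibroblasts and endothelial cells, were compared by share only.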

Results

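Single-cell RNA sequencing was used to measure gene expression in MC38 tumours, which grow from a mouse colon carcinoma line injected into the flank of C57BL/6 mice. The question named by the labels was how the cells of these tumours differ after treatment with SHP099, an allosteric inhibitor of SHP2, the phosphatase that Ptpn11 encodes and that carries signals from receptor tyrosine kinases to the RAS-ERK pathway. Treatment began 5 days after injection, when tumours averaged 100 mm3, and lasted 14 days. Mice received either SHP099 at 5 mg/kg into the stomach every day or PBS, with 6 mice in each of the 2 groups, and the labels also call the control mice untreated. Each group gave 1 library, and how many tumours entered a library is not given in the sources used here. The control library held 8245 barcodes with 126218180 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). The SHP099 library held 8263 barcodes with 112901642 UMIs. After filters and removal of doublets, 7688 control cells and 7702 SHP099 cells remained, with a median of 9162 and 10751.5 UMIs per cell. With 1 library per group, no difference described here has a replicate check, and the 95% intervals cover counting error only. Higher and lower below mean the SHP099 library set against the control library.

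Most cells of both tumour samples were either cells nearly free of the X-inactivation transcript Xist or mononuclear phagocytes. Classes were named from marker genes, so each name means cells that look like that type, and the suffix -like is dropped from here on. The Xist-negative cells made up 54.4% of control cells and 55.7% of SHP099 cells. They held a median of 24315.5 and 20157 UMIs per cell. Of the MC38 marker list, 4 genes were detected in them, Hmga2, Igf2bp2, Igf2bp3 and Tnfrsf12a, while the keratin gene Krt8 was at 0.115 and 0.0325 CPM (UMIs of the gene scaled to the total of the class). They also expressed the collagen gene Col3a1, at 1540 CPM in control and 2018 CPM in SHP099, against 15063 and 14145 CPM in the fibroblasts. Because epithelial markers were missing, they are described by their lack of Xist rather than by a cell type. Mononuclear phagocytes, which join macrophages and monocytes, made up 34.8% of control and 35.9% of SHP099 cells. Their parts went apart, though the border between them depends on clustering. Macrophage clusters made up 20.7% and 24.7%, the monocyte cluster 2.95% and 2.27%, and cluster 13, with markers of both, 11.2% and 8.92%.

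Lymphocytes were less frequent in the SHP099 library. T cells were 6.85% of control cells, with an exact binomial interval of 6.30 to 7.44%, and 5.23% of SHP099 cells, with an interval of 4.75 to 5.75%. The ratio of the shares was 0.763, with an interval of 0.673 to 0.866. NK cells were 1.26% and 0.688%, a ratio of 0.545 with an interval of 0.391 to 0.761. Fibroblasts, defined by Col1a1 and Col1a2, were lower at a ratio of 0.642, from 84 to 54 cells. Endothelial cells, defined by Cdh5 and Plvap, were higher at a ratio of 1.56, from 34 to 53 cells. The cDC2 cells, a class of conventional dendritic cells, gave 57 and 62 cells, migratory dendritic cells 19 and 15, and plasmacytoid dendritic cells 10 and 5, differences within their counting error. The cDC2 name is loose. By their own markers, 8 control and 7 SHP099 cells of that class looked like cDC1 cells, another conventional class. Only 5 and 13 looked like cDC2 cells. Shares of cells after dissociation also depend on how well each cell type survives it. No neutrophil, B cell, mast cell or epithelial cluster was found. The ratio for phagocytes, 1.03, was 0.853 when each library was clustered alone, where 425 phagocytes of the SHP099 library fell in a cluster that could not be named.

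**Figure D1:**
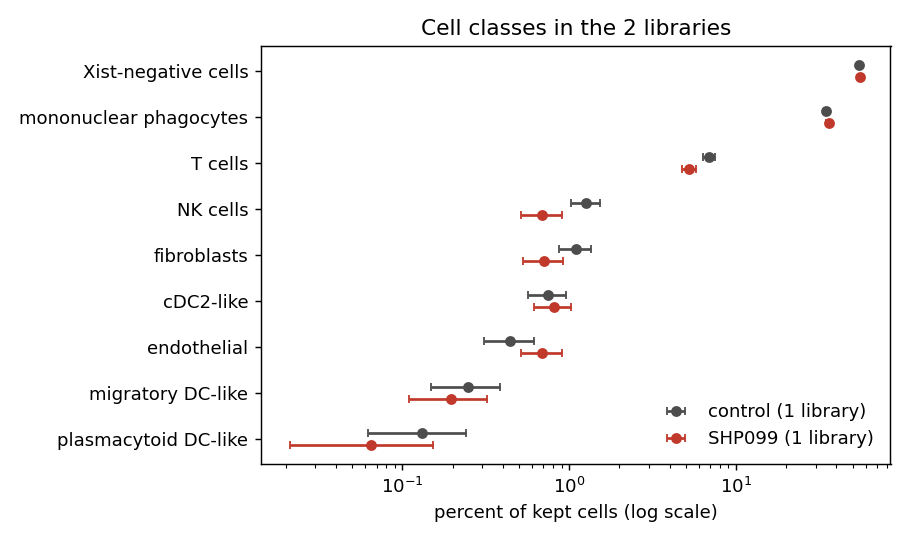
Share of kept cells in each class, in percent on a log axis, for the control library and the SHP099 library (1 each). Points are shares and bars exact 95% binomial intervals for counting error; T cells lay at 6.85% in control and 5.23% in SHP099, and NK cells at 1.26% and 0.688%.

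In mononuclear phagocytes, genes of cell division and of the type I interferon response were higher in the SHP099 library, while genes of hypoxia and glycolysis were lower. The mitosis list had a median log2 ratio of 1.06 over 27 measured members, above all of 10000 random lists matched on expression, as a description of these libraries. The median over all genes of the class was 0.05. Of the list's members, 25 were at least 1.5-fold higher and none was lower by that much. The proliferation antigen gene Mki67 was at 12.4 CPM in control and 40.9 CPM in SHP099, a log2 ratio of 1.68 with an interval of 1.45 to 1.99. The mitotic kinase gene Plk1 had a log2 ratio of 1.74, and the smallest differences in the list were those of Cks2 at 0.36 and Cenpa at 0.28. The DNA replication list had a median of 0.52, with 11 of 26 measured members at least 1.5-fold higher and none as much lower. Hells, a chromatin remodeller of replicating cells, had the largest ratio at 0.99, and the licensing factor gene Cdt1 the smallest at -0.07. With clusters weighted alike the DNA replication median was 0.34, and it was -0.02 within cluster 13 and -0.30 within cluster 14. The clusters of the class differed in size, with 620 control and 1070 SHP099 cells in cluster 1, 860 and 687 in cluster 13, and 812 and 671 in cluster 8. With the clusters weighted alike, the mitosis median was 0.79. With cells assigned by their own marker counts, which let cells of Xist-negative clusters into the class, it was 0.14.

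The type I interferon-stimulated list had a median log2 ratio of 0.58 in phagocytes, above all matched random lists. Its 42 measured members included 21 that were at least 1.5-fold higher and none that was as much lower. Ifit1, an antiviral protein that binds foreign RNA, was at 58.3 CPM in control and 124 CPM in SHP099, a log2 ratio of 1.08 with an interval of 0.96 to 1.22. Ifit3 had a log2 ratio of 1.15 and Usp18, a negative regulator of interferon signalling, 1.12. The largest ratios in the list were those of Ifit1bl1 at 1.70 and Ifit3b at 1.41, which share much sequence with Ifit1 and Ifit3, so that reads can be split between the copies. Isg15 had a log2 ratio of only 0.22 and Zbp1 -0.19. The interferon-gamma-responsive list did not move in the same way, with a median of -0.03 over 23 measured members, of which 5 were at least 1.5-fold lower and none as much higher, and a median of -0.13 with clusters weighted alike. Its members went both ways: Cxcl10, a T cell attractant, was higher at 0.57, while Cxcl9, another ligand of the same receptor, was lower at -0.85 with an interval of -0.90 to -0.79, and Nos2, the inducible nitric oxide synthase, at -1.78 with an interval of -2.30 to -1.48. Cd274, which encodes PD-L1, was lower at -0.80.

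Hypoxia and glycolysis genes in phagocytes had a median log2 ratio of -0.43 over 23 measured members, below all matched random lists, and 7 of them were at least 1.5-fold lower. The glucose transporter gene Slc2a1 was at 94.1 CPM in control and 47.1 CPM in SHP099, and Egln3, a hypoxia-induced prolyl hydroxylase, had a log2 ratio of -0.90. The members with the highest ratios, P4ha1 at 0.03 and Ddit4 at -0.05, did not differ beyond counting error. With clusters weighted alike the median was -0.30, and with cells assigned by their own marker counts it was -0.20. The mitochondrial share of UMIs in phagocytes was 2.25% in control and 3.17% in SHP099, and haemoglobin RNA was at 1.87 and 156 CPM.

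Chemokines of the phagocytes went in opposite directions. Ccl12, a monocyte attractant, was the chemokine with the largest ratio, from 457 CPM in control to 1254 CPM in SHP099, and Ccl7 had a log2 ratio of 0.86. Ccl5 was lower at -1.08 and Cxcl3 at -0.85, and the median of the chemokine and cytokine list was -0.30, with 3 of 21 measured members at least 1.5-fold higher and 7 as much lower. With clusters weighted alike that median was -0.18. Among alternative activation genes, whose list median was 0.23 over 12 measured members, the lectin gene Mgl2 was higher at 0.93 and the transcription factor gene Maf at 0.54, but Arg1, the arginase often used as their marker, was lower at -0.78 and Il10 at -0.84. Arg1 also marks cluster 8 and stood at -0.44 with clusters weighted alike. The mannose receptor gene Mrc1 had a log2 ratio of 0.25. The classical activation list had a median of -0.11, with 4 of 14 measured members at least 1.5-fold lower, among them Nos2 and Ccl5, and Il18 highest at 0.35. The MHC class II list had a median of -0.12, from H2-DMb2 at 0.40 to H2-Eb1 at -0.22, and no member moved by 1.5-fold over the class. Weighting clusters alike gave a class II median of -0.18. The lipid-handling and lysosomal list had a median of -0.14 over 20 measured members, with the lipase gene Lpl higher at 0.91 and the fatty acid carrier gene Fabp5 lower at -0.80. With cells assigned by their own marker counts, the classical activation and MHC class II medians were above 0.

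The genes with the largest ratios in phagocytes under the rule set for naming were Ch25h, the cholesterol 25-hydroxylase, at 1.65 with an interval of 1.45 to 1.92, then Ccl12 at 1.46, Pclaf at 1.24 and Top2a at 1.24. Cx3cr1, the fractalkine receptor, was at 209 CPM in control and 461 CPM in SHP099, Fcrls had a log2 ratio of 1.13, the tubulin regulator Stmn1 1.13 and the survivin gene Birc5 1.09. The smallest ratio under that rule was that of Ccl5, followed by the cystine transporter gene Slc7a11 at -1.07, the lectin gene Clec4d at -1.02, Slc2a1 at -0.99, Pitpnc1 at -0.94, Ninj1 at -0.92, Ly6i at -0.90, the lysosomal galactosidase gene Gla at -0.88 and the protease gene Adam8 at -0.84. Ly6i and Ccl12 were among the genes that mark clusters 13 and 1. Weighting clusters alike left Ccl12 at 1.26 and Cx3cr1 at 1.02, and moved Pclaf to 0.82 and Adam8 to -0.56.

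**Figure D2:**
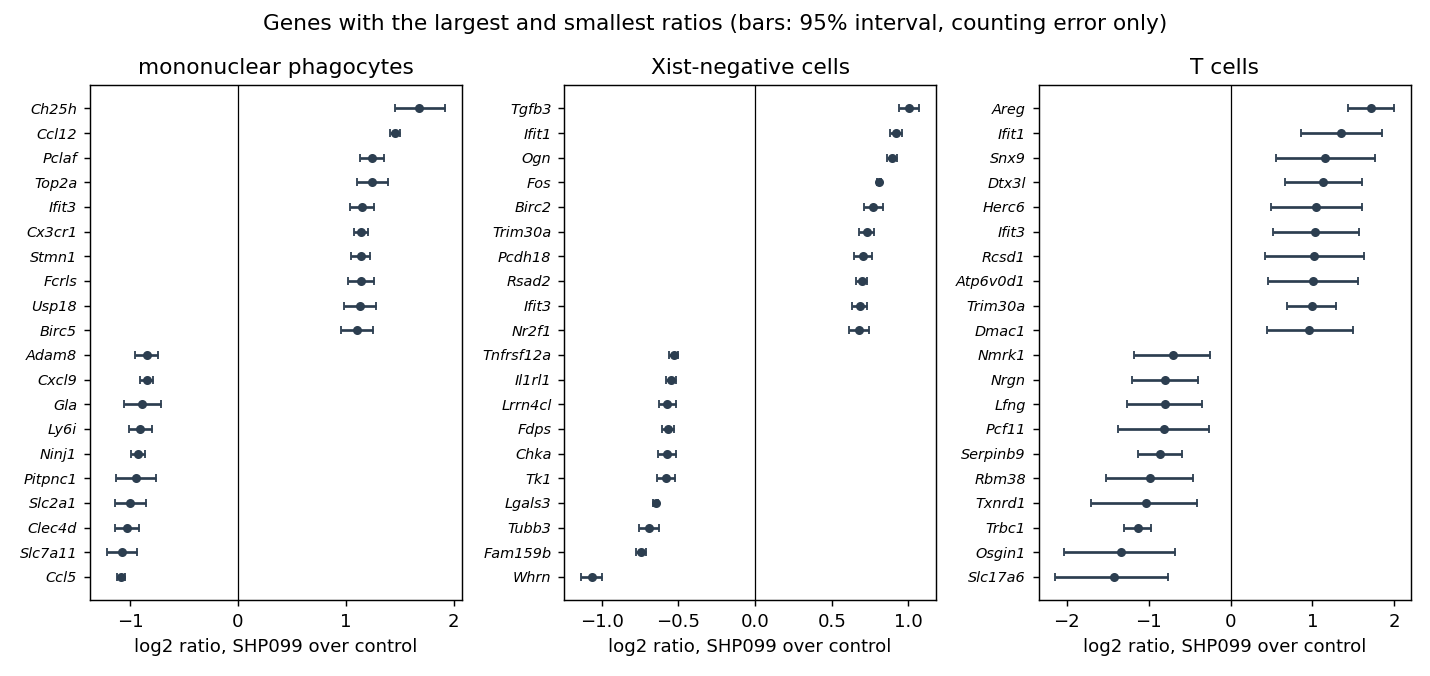
Log2 ratio of SHP099 over control for the genes with the largest and smallest ratios under the naming rule, which leaves out genes at low levels, in phagocytes, Xist-negative cells and T cells, from summed UMIs of 1 library per group. Bars are 95% intervals for counting error; the highest points shown are Ch25h at 1.65, Tgfb3 at 0.99 and Areg at 1.71.

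The same differences appeared in the share of phagocytes with at least 1 UMI of a gene, taken after drawing every cell down to 2000 UMIs. That step left out 319 of the control and 317 of the SHP099 phagocytes, whose median depths were 4325.5 and 4207.5 UMIs. T cells, which were taken to lack these genes, served as background, at median depths of 2356 and 2035 UMIs, with 198 and 199 cells left out. Arg1 was detected in 44.4% of control and 31.0% of SHP099 phagocytes, with T cell shares of 0.304% and 0% of 204 cells, which allows up to 1.79%. Without drawing down, the Arg1 shares were 52.5% and 38.9%. Cxcl9 was detected in 35.6% and 22.9% of phagocytes, and in 43.1% and 30.4% at full depth, against T cell shares of 0.304% and 0.980%. Ccl12 was detected in 28.2% and 48.7%, and in 35.5% and 58.5% at full depth, against 1.52% of control T cells and 4 of 204 SHP099 T cells. Cx3cr1 was detected in 28.8% and 50.6%, and in 44.3% and 66.9% at full depth, against 8.21% and 5.88% in T cells. These T cell shares exceed those of the other genes given, so T cells may not be a clean background for Cx3cr1.

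Mki67 was detected in 1.82% of control phagocytes, with an interval of 1.32 to 2.45%, and in 5.35% of those of the SHP099 library, with an interval of 4.49 to 6.32%, after drawing down to 2000 UMIs. At full depth the shares were 4.11% and 10.9%. No class could be taken to lack dividing cells, so these shares have no independent background for free RNA. The monocyte cluster 5, itself part of the class, is given as a part that should divide little, at median depths of 2473 and 2576 UMIs and with 62 and 34 cells left out. There 0.606% and 0% of cells had a Mki67 UMI, and the count of 0 among 141 cells allows up to 2.58%.

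In Xist-negative cells, type I interferon-stimulated genes and matrix genes were higher in the SHP099 library. The interferon-stimulated list had a median log2 ratio of 0.43 over 35 measured members, above all matched random lists, with 10 members at least 1.5-fold higher. Ifit1 was at 87.6 CPM in control and 166 CPM in SHP099, a log2 ratio of 0.92 with an interval of 0.88 to 0.96. Rsad2, the antiviral protein viperin, had a log2 ratio of 0.69, Ifit3 0.68 and Trim30a 0.72, while Isg15 had 0.14 and the nucleic acid sensor gene Zbp1 -0.29. The interferon-gamma-responsive list had a median of -0.11, with no member moved by 1.5-fold in either direction. It held the GTPase genes Gbp2 at -0.34 and Gbp4 at -0.48, and Irgm2 at 0.22. Clusters 2, 0 and 11 held most of these cells in control, and clusters 6, 7 and 2 in SHP099. With clusters weighted alike the interferon-stimulated median was 0.27 and the interferon-gamma median -0.27, while Isg15 moved to -0.03, Cxcl9 from 0.11 to -0.32 and Cxcl10 from 0.12 to -0.05.

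The fibroblast activation and matrix list had a median of 0.39 over 11 measured members in Xist-negative cells. The 2 that were at least 1.5-fold higher were the matricellular gene Postn at 1.49 and the collagen gene Col1a1 at 1.20, which remained low at 12.9 and 30.3 CPM. The epithelial-mesenchymal list had a median of 0.09 over 16 measured members, or 0.03 with clusters weighted alike, with the protease gene Mmp9 at 0.84 and the integrin gene Itga5 at -0.36. Among single genes, the growth factor gene Tgfb3 was at 28.5 CPM in control and 57.3 CPM in SHP099. The proteoglycan gene Ogn had a log2 ratio of 0.89, Birc2 0.76, the protocadherin gene Pcdh18 0.70 and the transcription factor gene Nr2f1 0.67. Lower were Whrn at -1.05, Fam159b at -0.74, the neuronal tubulin gene Tubb3 at -0.68, the galectin gene Lgals3 at -0.65, the thymidine kinase gene Tk1 at -0.58, Chka at -0.57, Fdps at -0.57, Lrrn4cl at -0.57, Il1rl1 at -0.55 and Tnfrsf12a at -0.53. Ogn marks cluster 6, and Tgfb3, Birc2, Ifit1 and Rsad2 mark cluster 7, clusters that held more of the SHP099 cells. With clusters weighted alike, Ogn stood at 0.44, Birc2 at 0.51, Rsad2 at 0.43, Tgfb3 at 0.73 and the matrix list at 0.19, and Tk1 at -0.28.

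Immediate-early and dissociation-stress genes had a median of 0.31 in Xist-negative cells, or 0.14 with clusters weighted alike, with the transcription factor gene Fos from 564 CPM in control to 989 CPM in SHP099 and the chaperone gene Hsp90aa1 at -0.39. The same list had medians of 0.20 in phagocytes and 0.24 in T cells. In Xist-negative cells, the nuclear RNA Malat1 was at 17827 CPM in control and 24334 CPM in SHP099, haemoglobin RNA at 30.8 and 112 CPM, and the mitochondrial share of UMIs at 3.09% and 3.60%. DNA replication genes had a median of -0.23 over 28 measured members, none of them moved by 1.5-fold, with Pcna at -0.40 and Cdt1 at -0.45. That median was -0.03 with clusters weighted alike, while within single clusters it ran from -0.26 in cluster 0 and -0.25 in cluster 7 to 0.09 in cluster 11. The mitosis list had a median of -0.14 over 30 measured members, with Ube2c at -0.47, but its sign depended on the mix of clusters, since the median was 0.08 with clusters weighted alike.

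In T cells, type I interferon-stimulated genes were higher in the SHP099 library, with a median log2 ratio of 0.77 over 39 measured members, above all matched random lists. Of these, 25 were at least 1.5-fold higher. Ifit1 was counted 56 times in control and 101 times in SHP099, a log2 ratio of 1.34 with an interval of 0.86 to 1.85. Ifit3 had a log2 ratio of 1.03, the ubiquitin ligase gene Herc6 1.03 and Trim30a 0.99, and Ifi44 had 1.92. Isg15 had 0.51, or 0.32 with clusters weighted alike, and Irf9 -0.21, within its counting error. The CD8-rich cluster 3, which held 438 control and 290 SHP099 cells, gave a median of 0.75 on its own. A list made up mainly of genes of other cells was higher as well. The fibroblast activation and matrix list, not chosen in advance for T cells, had a median of 0.74 over 8 measured members and 0.87 in cluster 3. That list also holds Thy1, which T cells express. When cells were drawn down to 2000 UMIs, which left out 198 of the control and 199 of the SHP099 T cells, the median was 0.44.

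The T cell class also held more regulatory T cells in the SHP099 library. Among T and NK cells clustered on their own, the regulatory subset, marked by Foxp3, Il2ra and Izumo1r, was 75 of 624 cells in control and 107 of 456 cells in SHP099. The interval of the control share was 9.57 to 14.8%, and the SHP099 share was 23.5%, with an interval of 19.6 to 27.6%. The CD8 subset was 31.2% and 29.8% of T and NK cells, and 41.3% and 34.9% fell in sub-clusters that could not be named. Of these, sub-cluster 0, led by Ramp3 and Tnfsf11, held 124 control cells and 39 SHP099 cells. Sub-cluster 2, with Ly6c2 and the interferon-stimulated gene Ifit3 among its top genes, held 118 of 624 and 112 of 456 cells. The weighting of T cells used clusters 3 and 17, not these sub-clusters. It does not remove this shift from the interferon-stimulated median. The regulatory T cell list, whose members define the regulatory subset, had a median log2 ratio of 0.50 over 10 measured members in all T cells, with Foxp3 at 0.71. That median was -0.06 with clusters weighted alike and -0.32 in cluster 3 alone. Areg, a growth factor made by tissue regulatory T cells and a marker of cluster 17, was at 102 CPM in control and 335 CPM in SHP099. Its log2 ratio of 1.71 was 1.03 with clusters weighted alike and 0.72 in cluster 3.

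The cytotoxic genes of T cells differed little, and inhibitory receptor genes went both ways. The cytotoxic list had a median of -0.14 over 20 measured members, below all but 0.42% of matched random lists. Its counting interval was -0.22 to -0.05. Of its members, 1 was at least 1.5-fold lower and none as much higher, with the granzyme gene Gzmc at 0.55 and the NK receptor gene Klrd1 at -0.45. Gzmb was at 1179 CPM in control and 1009 CPM in SHP099, and the perforin gene Prf1 had a log2 ratio of -0.14 with an interval of -0.46 to 0.17. Granzyme genes share sequence, so their separate values are uncertain. Ifng had a log2 ratio of -0.31 with an interval of -0.65 to 0.02, and with clusters weighted alike it stood at -0.13 and Prf1 at -0.00. The inhibitory receptor list had a median of -0.06 over 14 measured members in all T cells, -0.16 with clusters weighted alike, and -0.31 in cluster 3 alone. In that cluster 2 members were at least 1.5-fold higher and none was as much lower. Over all T cells Pdcd1, which encodes PD-1, was lower at -0.55 with an interval of -0.82 to -0.29, Lag3 at -0.57 and Cd160 at -0.61, while the ectonucleotidase gene Entpd1 was higher at 1.19. The median of the cytotoxic list was -0.05 with clusters weighted alike and 0.07 with doublets kept.

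Pdcd1 was detected in 36.8% of control and 26.0% of SHP099 T cells after drawing down to 2000 UMIs, and in 37.8% and 26.3% at full depth. Gzmb was detected in 52.6% and 55.4%, and in 51.6% and 54.6% at full depth, a direction opposite to that of its CPM, so that no order was read from it. Xist-negative cells served as background, at median depths of 24315.5 and 20157 UMIs and with 78 and 30 cells left out. In them Pdcd1 was detected in 0% and 0.0469% of cells, where the count of 0 among 4106 cells allows up to 0.0898%, and Gzmb in 0.146% and 0.0469%.

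Mitosis genes had a median of 0.54 in T cells, with 9 of 27 measured members at least 1.5-fold higher, led by the cyclin B1 gene Ccnb1 at 1.98 and Cenpf at 1.28. Yet the dividing CD8 sub-cluster 4, with Ube2c and Birc5, held 56 of 624 T and NK cells in control and 32 of 456 in SHP099. Free RNA of Xist-negative cells, put at 5.28% in control and 6.21% in SHP099 T cells, was not subtracted for this list. The interferon-gamma-responsive list had a median of 0.22 over 20 measured members, and it was 0.05 with clusters weighted alike and -0.04 with doublets kept. Naive and memory genes had a median of 0.07, with the migration regulator Klf2 at 0.90 and the interleukin-7 receptor gene Il7r at -0.39. MHC class II genes, which mouse T cells express little, had a median of 0.67, but 0.31 with clusters weighted alike, -0.04 in cluster 3 alone, and -0.16 when each cell was given the same weight. Col3a1, a gene of other cells, was at 84.1 CPM in control and 144 CPM in SHP099 T cells, and ribosomal protein genes made up 33.2% and 29.6% of their UMIs. Beyond those already named, the T cell genes with the largest ratios under the naming rule were Snx9 at 1.14, Dtx3l at 1.12, Rcsd1 at 1.01, Atp6v0d1 at 0.99 and Dmac1 at 0.95. The lowest were Slc17a6 at -1.40, Osgin1 at -1.32, Trbc1 at -1.13, Txnrd1 at -1.02, Rbm38 at -0.97, the granzyme inhibitor gene Serpinb9 at -0.86, Pcf11 at -0.80, Lfng at -0.79, Nrgn at -0.79 and Nmrk1 at -0.70. Trbc1 shares reads with Trbc2, and Slc17a6 and Nmrk1 mark sub-cluster 0.

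**Figure D3:**
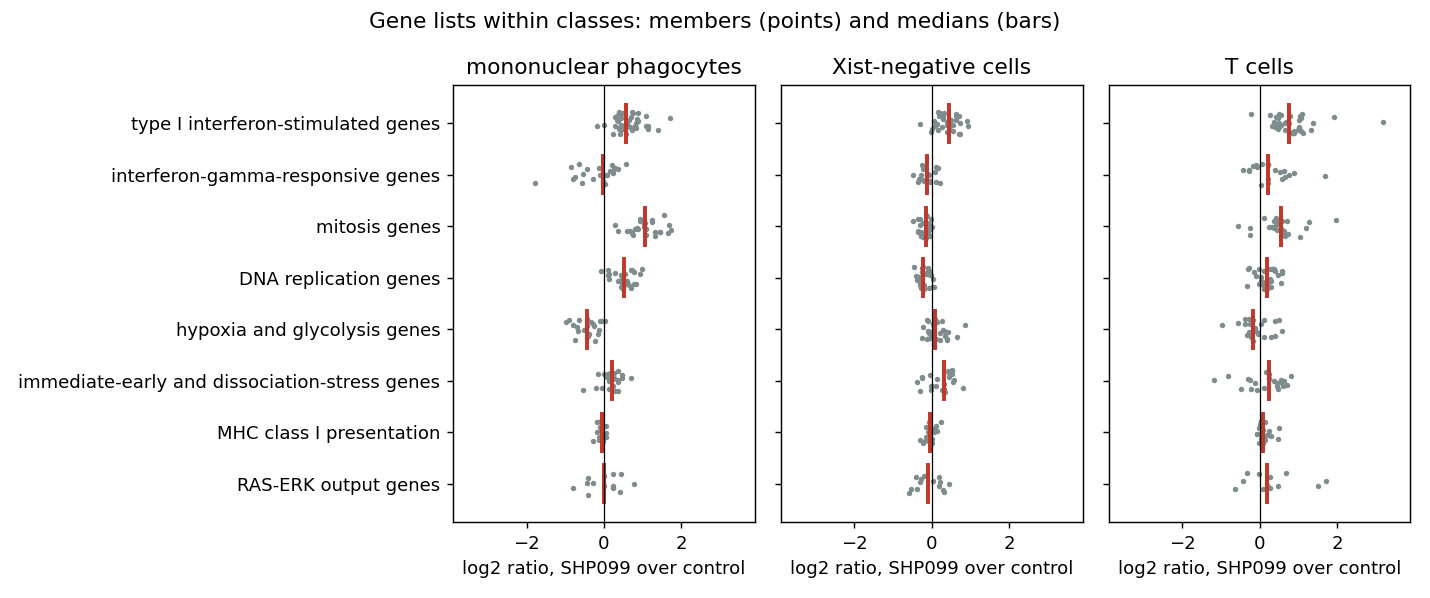
Log2 ratio of SHP099 over control for the measured members of 8 gene lists (points) and their medians (bars) in 3 cell classes, 1 library per group. The interferon-stimulated medians lie at 0.58 in phagocytes, 0.43 in Xist-negative cells and 0.77 in T cells, and the mitosis medians at 1.06, -0.14 and 0.54.

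The RNA of the inhibitor's target differed little, and genes of the pathway it feeds had class medians of different sign and went apart between clusters. Ptpn11 was at 53.8 CPM in control and 55.5 CPM in SHP099 Xist-negative cells, 26.9 and 27.8 CPM in phagocytes, and 38.2 and 33.8 CPM in T cells, differences within counting error. An inhibitor of the protein need not alter its RNA. The list of SHP2 and its partners had medians of 0.01 in Xist-negative cells, 0.05 in phagocytes and 0.05 in T cells. RAS-ERK output genes had a median of -0.09 in Xist-negative cells over 14 measured members, below all but 2.2% of matched random lists and with a counting interval of -0.15 to -0.03. It was -0.04 with clusters weighted alike, and 0.03 when members with as little as 1 UMI were counted. Among them Ccnd1, which encodes cyclin D1, was lower at -0.29, Etv5 at -0.37, Etv4 at -0.23 and the urokinase receptor gene Plaur at -0.59, while the feedback regulators Dusp6 and Spry2 were higher at 0.19 and 0.44, and Spry4 had 0.09. Ccnd1 stood at -0.11 with clusters weighted alike, Etv4 at -0.03 and Spry2 at 0.18. Within single clusters the median was lowest in cluster 4 at -0.40 and cluster 7 at -0.29. In phagocytes the median of the list was -0.00, but 0.12 with clusters weighted alike and 0.24 without cluster 14, and it was 0.31 in cluster 1, 0.19 in cluster 8 and -0.28 in cluster 5. The class held Dusp6 at 0.77, Ccnd1 at 0.43, Etv5 at 0.24 and Fosl1 at -0.80. In T cells the list median was 0.20, or 0.09 with clusters weighted alike, led by Areg and by Myc, which had 7 UMIs in control and 15 in SHP099.

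The STING pathway, a DNA-sensing route to type I interferon, had list medians of 0.13 in Xist-negative cells, -0.03 in phagocytes and 0.05 in T cells. Tmem173, which encodes STING, had log2 ratios of 0.10, -0.02 and 0.26 in these classes, Tbk1 0.13, -0.03 and 0.44, and Irf3 0.17, 0.23 and -0.03. Tmem173 stood, with clusters weighted alike, at -0.05 in Xist-negative cells and 0.09 in T cells. The receptor gene Ifnar1 was higher in Xist-negative cells at 0.41 and in phagocytes at 0.36. UMIs of Ifnb1, the interferon-beta gene, numbered 6 in control and 55 in SHP099 Xist-negative cells, found in 0.0956% and 0.350% of cells. Both levels, 0.0576 and 0.596 CPM, lie near or below the prior of 0.5 CPM, so the log2 ratio of 0.98, or 0.74 with clusters weighted alike, is drawn towards 0 by that prior. Some cells held several of these UMIs, so they are not independent counts and no interval is given. Phagocytes gave 3 and 1 UMIs of Ifnb1 and T cells none.

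Hypoxia and glycolysis genes had medians of 0.09 in Xist-negative cells and -0.17 in T cells. Among Xist-negative clusters the median was 0.35 in cluster 0, which is marked by Ero1l, with 8 of 27 measured members at least 1.5-fold higher, and 0.22 in cluster 10. Oxidative phosphorylation genes had medians of -0.08 in Xist-negative cells, -0.03 in phagocytes and 0.04 in T cells. Medians of the p53 target list were -0.02, 0.01 and 0.12 in the same order, and those of the unfolded protein and stress response list -0.03, 0.17 and 0.15. MHC class I genes had medians of -0.05 in Xist-negative cells, -0.05 in phagocytes and 0.09 in T cells. DNA replication genes had a median of 0.19 in T cells. With clusters weighted alike, these medians ran from -0.24 for hypoxia genes in T cells to 0.19 for DNA replication genes in T cells. MHC class I genes then stood at -0.14 in Xist-negative cells and -0.13 in phagocytes.

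Within single clusters, the interferon-stimulated median was above 0 in all 13 clusters with at least 100 cells in each library. It ranged from 0.09 in cluster 4 to 0.54 in cluster 8 outside T cells, and was 0.75 in the T cell cluster 3. The interferon-gamma median was below 0 in each of the phagocyte and Xist-negative clusters, from -0.48 in cluster 0 to -0.07 in cluster 8, and 0.24 in cluster 3. Mitosis genes in phagocytes were higher in cluster 8 at 1.80, cluster 1 at 0.80 and cluster 13 at 0.77, and lower in the monocyte cluster 5 at -0.49 and in the shallow cluster 14 at -0.53. Hypoxia and glycolysis genes were lower in clusters 1, 5, 8 and 13 and higher in cluster 14, at 0.34, and in the Xist-negative clusters 0 and 10.

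**Figure D4:**
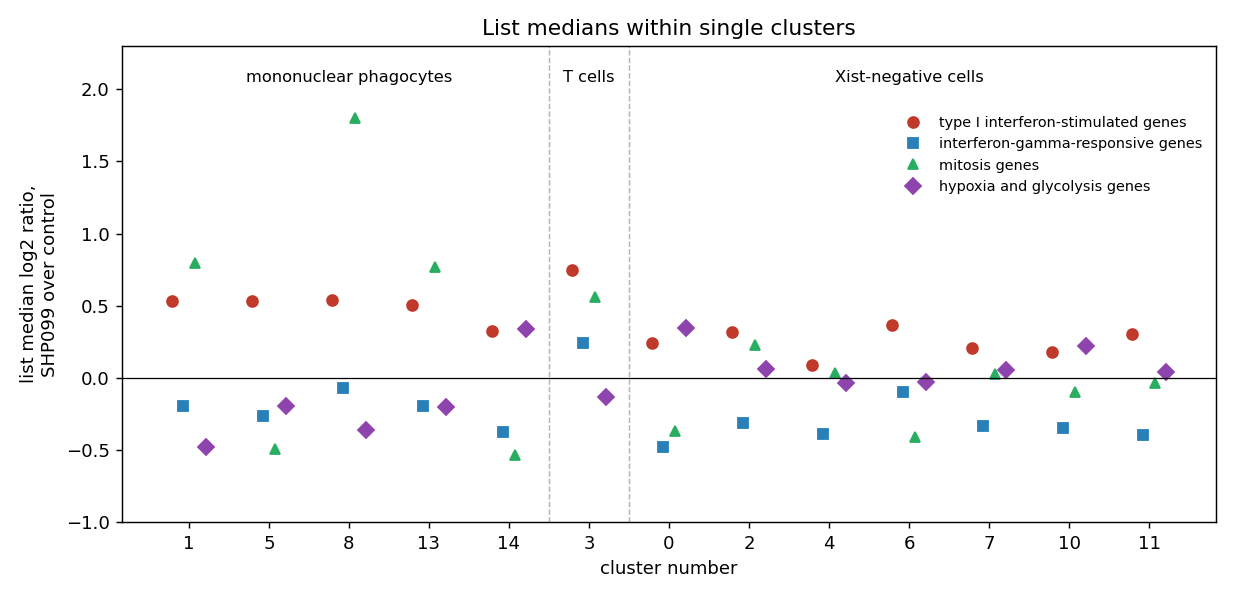
Median log2 ratio of SHP099 over control for 4 gene lists within the larger clusters, grouped by class, 1 library per group. The interferon-stimulated medians lie above 0 in all 13 clusters, and the mitosis median of cluster 8 lies at 1.80.

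Summed over all kept cells, as a bulk library would show them, the largest ratios under the naming rule, which leaves out haemoglobin and genes at low levels, were those of Ccl12 at 1.68, Cx3cr1 at 1.31, the proteoglycan gene Aspn at 1.23, Postn at 1.17 and Ifit1 at 0.93. The smallest under that rule were those of Fam159b at -0.77, Upp1 at -0.59, Lrrn4cl at -0.58, the water channel gene Aqp1 at -0.58 and Lgals3 at -0.58. These sums mix the makeup of the samples with expression inside cells. The interferon-stimulated list had a median of 0.50 over all cells and the interferon-gamma list -0.12.

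On GRCm38, with GENCODE M21 gene models and 1-based coordinates, Ptpn11 lies on chromosome 5 from 121130533 to 121191397, minus strand. Ifit1 lies on chromosome 19 from 34640871 to 34650009, plus strand, and Ch25h on the same chromosome from 34473778 to 34475164, minus strand. Ccl12 lies on chromosome 11 from 82101845 to 82103400, plus strand, and Mki67 on chromosome 7 from 135689784 to 135716361, minus strand. Cxcl9 lies on chromosome 5 from 92321347 to 92328079, minus strand. Tgfb3 lies on chromosome 12 from 86056745 to 86079041, minus strand, and Areg on chromosome 5 from 91139599 to 91148432, plus strand. The counts are 3' tags assigned to whole genes, so they do not resolve exons or transcript forms.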

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

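A value is counted as reversed only if it changed sign and its counting interval in the report excluded no difference, and as moved if it left that interval otherwise. Of 110 values of the main results under alternatives chosen before the data were examined, 90 kept their size, 20 moved and 0 reversed. Of 2052 other values, 1769 kept their size, 274 moved and 9 reversed. Under alternatives added later, 3 of 10 main values kept their size and 7 moved, and of 297 others 225 kept their size, 64 moved and 8 reversed. By sign alone, more values lay on the other side: 3 of 8 for the phagocyte share ratio, and among single genes 31 of 572 in T cells, 34 of 572 in phagocytes and 13 of 528 in Xist-negative cells. Among list medians these were 22 of 269, 23 of 270 and 9 of 209. No paired analysis was possible because each group has 1 library. Where no reason is given below, the cause was not tested.

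The ratio of NK cell shares stayed between 0.502 and 0.566 in all 8 alternatives. The ratio of T cell shares was 0.606 with clusters of thinned cells. The ratio of phagocyte shares was 0.909 with 500 genes and 10% mitochondrial counts as limits, 0.957 at resolution 2.0 and 0.853 with each library clustered alone, where 425 SHP099 phagocytes fell in an unnamed cluster.

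In phagocytes the mitosis median, 1.06 in the report, was 0.87 with the stricter limits, 1.22 with doublets kept, 1.23 at resolution 0.5, 0.14 with classes from each cell's own markers, 0.78 with a prior of 5 CPM, 0.84 with members at 50 CPM or more, 0.79 with clusters weighted alike and 1.25 without cluster 14. With own markers, 712 control and 674 SHP099 cells of Xist-negative clusters entered the phagocytes, and Birc5 stood at -0.0657, the MHC class II median at 0.0677 and the classical activation median at 0.14. The hypoxia median, -0.43 in the report, was -0.45 with doublets kept, -0.47 at resolution 0.5, -0.39 with each library alone, -0.20 with own markers, -0.48 with scaling by the median ratio, -0.47 with per-cell means, -0.45 with thinned cells, -0.30 with clusters weighted alike and -0.46 without cluster 14. The interferon-stimulated median was 0.49 with a prior of 5 CPM.

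In Xist-negative cells the interferon-stimulated median was 0.38 with a prior of 5 CPM and 0.27 with clusters weighted alike. That weighting also gave -0.27 for the interferon-gamma median, 0.0836 for the mitosis median, -0.0474 for Cxcl10, -0.32 for Cxcl9, -0.0262 for Isg15 and 0.13 for Mki67. The RAS-ERK median was 0.0265 with members at 1 UMI or more. Prf1, with 31 and 5 UMIs, was at 0.30 with thinned cells.

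In T cells the interferon-stimulated median was 0.44 with thinned cells and 0.60 with clusters weighted alike. With doublets kept, the interferon-gamma median was -0.0419, the cytotoxic median 0.0651 and Cxcl10 -0.11. The MHC class II median was -0.16 with per-cell means and -0.0357 in cluster 3 alone. The regulatory T cell median was -0.0588 with clusters weighted alike and -0.32 in cluster 3 alone.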

Other observations

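The Xist-negative cells split into clusters of distinct makeup that differed in size between the libraries. Cluster 6, with the matrix genes Aspn, Ogn and Dcn, held 575 control and 857 SHP099 cells, and cluster 7, with H19, Ptn and Ifit1, held 426 and 776. The dividing cluster 2, with histone genes and Top2a, held 916 and 672 cells, and cluster 0, with the hypoxia genes Ero1l and Bnip3, held 674 and 595.

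Among phagocytes, cluster 1, with Ccl12, Cd72 and C1qa, made up 8.06% of control and 13.9% of SHP099 cells. Cluster 8, with Pf4, Mmp12, Spp1 and Arg1, made up 10.6% and 8.71%, and cluster 13, with Il1b and Ly6c2, 11.2% and 8.92%. Mki67 UMIs were found in 110 control and 302 SHP099 phagocytes. These genes were chosen after their values were seen, as the ones that define the clusters.

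For the clusters nearly free of Xist, the tests on depth and on Xist against fibroblasts were chosen only after the result was seen. Their median depth was 5.45 times that of the other cells, so shallow counts are not the reason. Their Xist level was 0.00286 of that in host fibroblasts. The clusters were set apart by low Xist, so a low ratio was fixed in advance and does not test their identity. The spread of chromosome medians against host classes was at least 1.69 times the largest spread among host classes. The lowest spread was 0.133, against at most 0.0784 among host classes. Chromosome 15 was higher against each host class, at 0.465 against phagocytes, 0.395 against T cells, 0.280 against fibroblasts and 0.389 against endothelial cells. Y-linked genes gave 0 UMIs in control and 1 in SHP099 Xist-negative cells. These values argue against host cells and go with cells of the injected line that carry chromosome gains or losses. Krt8 and Epcam were missing, so an epithelial identity was not shown.

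For the interferon-stimulated genes, the tests on the mix of clusters and on free RNA in T cells were chosen only after the result was seen. Subtracting free RNA of phagocytes left a median of 0.42 in Xist-negative cells and 0.745 in T cells, and subtracting that of Xist-negative cells left 0.747 in T cells. Weighting clusters alike left 0.27, or 62.6% of the value, and weighting cells alike by their immediate-early share left 0.32, or 73.3%. Cluster 7 is itself marked by Ifit1 and Rsad2, so weighting clusters alike can remove part of the interferon difference itself. The immediate-early share was measured after treatment and need not stand for dissociation alone. Neither drop therefore decides whether a shift of clusters or stress during dissociation is part of the cause. Both weightings were coarse and were not combined, so these values cannot tell how much either accounts for. Whether SHP099 or a difference between tumours is behind any remainder was not tested.

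For the mitosis genes of phagocytes, the tests on the mix of clusters were chosen only after the result was seen. SHP099 phagocytes with at least 3 mitosis UMIs held 7.86% of the level of genes specific to Xist-negative cells, against 4.43% in those without. Those genes were picked for a low level in phagocytes as a class. The cells with at least 3 mitosis UMIs were 43.9% of SHP099 phagocytes, so a low value was largely fixed in advance. Whether doublets add to the mitosis genes therefore cannot be told from this value. The phagocytes with a Mki67 UMI held 18.4% in control and 6.14% in SHP099. Their Xist level was 1057 CPM in control and 1526 CPM in SHP099. With at least 3 mitosis UMIs it was 1002 and 1220 CPM, against 1036 and 1089 CPM without any. Doublets with cells nearly free of Xist would lower that level. The Xist values and the lower share in SHP099 argue against doublets as the main source of the higher mitosis genes there. Subtracting free RNA raised the median to 1.48, but subtraction from low levels, with negative values cut off, can enlarge ratios. The rise itself is therefore not read as a result. Weighting clusters alike left 0.79, or 75.1%, which does not decide whether a shift of clusters is part of the cause. Classes from each cell's own markers gave 0.14, but took in 712 control and 674 SHP099 cells of Xist-negative clusters. Xist-negative cells held medians of 24315.5 and 20157 UMIs, against 4325.5 and 4207.5 in phagocytes, so such cells weigh heavily in summed counts. How much of the drop they explain was not tested. With 1 library per group, no cause can be assigned to the higher mitosis genes.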
